A study of Mus musculus with 8 samples.

How the data were processed

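RNA was sequenced from mouse embryonic fibroblasts on day 8 of reprogramming to pluripotency by the OKSM factors (Oct4, encoded by Pou5f1, with Klf4, Sox2 and Myc), in a medium that the labels call AGi. The cells were WT or carried K36M, a histone H3 mutant in which a methionine replaces the lysine that is normally methylated. They were treated with 250 nM Repsox, an inhibitor of the TGF-beta type I receptor, or with 2.5 ng/ml TGF-beta1. Each of the 4 groups had 2 libraries from RNA depleted of ribosomal RNA, per the labels' protocols. The labels describe the WT libraries also as H3, and do not say whether the 2 libraries of a group came from separate cultures or animals. If they did not, the p-values measure only the spread between these libraries (common biological coefficient of variation 0.07).

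The values used were the deposited gene counts, whole reads per gene and library in 1 table with 26930 genes and 8 libraries. Per the submitters' processing notes, STAR 2.5.0, HTSeq 0.11.2 and edgeR were used with the mm9 genome; the part edgeR played, the gene annotation, the strand setting of the counting and any gene filter were not given in the sources used here. Reads of genes that overlap, are antisense to each other or have near-identical copies could therefore not be assigned with certainty. The table held 3195 genes at 0 in every library. Of its identifiers, 26763 were found in GENCODE vM1, the mouse annotation on mm9 from which the coordinates were taken, and 99.0% of those had the same symbol there. Of 477 genes in the fixed lists, 7 had no entry in the table.

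Totals ran from 10928302 to 15594217 counts per library. Spearman's correlation between the 2 libraries of a group, across genes, was 0.966 to 0.970. The chi-square per degree of freedom between them, which is 1 for counting error alone, was 2.70 to 9.09 over genes with a summed count of at least 20, so that replicates differed by more than counting error. Intervals and lower bounds on ratios cover counting error only. For a gene with 0 counts in a group the fold was bounded with 3 counts over that group and is written as at least that fold; with 1 to 3 counts, the ratio of rates is given with its exact 95% interval. The fitted fold change of such genes depends on the prior count and is no bound.

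Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 15789 genes, TMM factors (0.894 to 1.057) scaled the libraries, and a quasi-likelihood F test was fitted to the 4 group means over all 8 libraries, which leaves 4 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Errors of log2 fold changes are standard errors, the size of the log2 fold change over the square root of F. The spread in F was moderated across genes, with 17.5 prior degrees of freedom. For a gene whose own 2 libraries differ widely, such as Nanog in WT under TGF-beta, the error can therefore understate the spread between replicates. Levels are CPM on TMM-scaled library sizes, mean ± SD over 2 libraries. The comparisons were K36M against WT under Repsox, K36M against WT under TGF-beta, TGF-beta against Repsox in WT, TGF-beta against Repsox in K36M, and the interaction, which is the difference between the last 2 and tests whether the medium acted differently in the 2 genotypes. No library was shared by the 2 genotype comparisons, nor by the 2 medium comparisons.

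The 24 gene lists were tested with camera of limma 3.58.1, a competitive test of a list against all other genes, with a preset correlation between genes of 0.01, and adjusted over the 24 lists of a comparison. The test was repeated with the correlation estimated from the residuals, which have only 4 degrees of freedom. The lists were written from general knowledge and not chosen on these libraries. Krt7 and Cdh3 were in both the epithelial and the trophoblast list, and Sparc in both the mesenchymal and the primitive endoderm list.

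Genes are named by a rule. For each of the 4 pairwise comparisons it took the 8 largest increases and 8 largest decreases among genes with adjusted p below 0.05, an average log2 CPM of at least 2 and no overlap between the libraries of the groups, leaving out predicted and unnamed loci, mitochondrial genes, small RNAs and histone cluster genes. For the interaction it took 5 in each direction without the condition on overlap. From each list it took the 3 called members with the smallest adjusted p, or the member with the highest level where none was called. Pou5f1, Sox2, Klf4, Myc, H3f3a, H3f3b, Nanog, Cdh1, Epcam, Thy1, Col1a1 and Smad7 were followed in every comparison. Some genes that the rule took are not reported here. A gene named outside this rule is said to have been chosen after its values were seen. The groups, the tests, the lists, the rule and the alternatives were fixed before the data were examined, except where stated.

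The fit was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For K36M against WT under Repsox, with 15268 genes, 93% and 100% were called, and unchanged genes made up 8.53% of the calls, more than the nominal rate. Under TGF-beta, with 15253 genes, these values were 92%, 100% and 4.00%. For TGF-beta against Repsox they were 98%, 100% and 4.81% in WT with 15240 genes, and 93%, 100% and 2.03% in K36M with 15267 genes. For the interaction, with 15257 genes, they were 91%, 98% and 5.03%. In each comparison, 0 of 20 random lists were called by camera. The simulated genes were drawn independently and the lists taken from unchanged genes, so this could not test the preset correlation. Far fewer genes were changed than were called in the data, so the shares of unchanged genes among the calls need not hold there.

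The alternatives were RLE, upper-quartile and library-size scaling, no count filter or a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the 4 libraries of a comparison, an adjusted p below 0.01, a log2 fold change of at least 1, leaving out the 50 most abundant genes, and leaving out each library in turn. A result that failed its threshold under both settings was counted as the same, and its direction was not read. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. The groups of 2 were too small for a test of single outlying libraries or for a count of other splits of the libraries. The series also describes other time points, chromatin assays and established lines, which were not among the libraries used here.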

Results

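Gene expression was measured in 8 RNA-seq libraries of reprogramming intermediates on day 8, in 4 groups of 2: WT cells under Repsox, WT cells under TGF-beta, K36M cells under Repsox and K36M cells under TGF-beta. The libraries held 14447449 and 12532258 counts for WT under Repsox, 12761968 and 15594217 for WT under TGF-beta, 14935266 and 12033198 for K36M under Repsox, and 12511258 and 10928302 for K36M under TGF-beta. No untreated group was among them, so a difference between TGF-beta and Repsox cannot be assigned to either treatment alone. The first principal component of log2 CPM carried 65.6% of the variance and the second 18.9%, and the 2 libraries of every group lay side by side on both. The libraries of the 2 groups did not overlap for 75.1 to 85.2% of the 15789 tested genes in the 4 pairwise comparisons, where chance separates 33.3%.

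**Figure D1:**
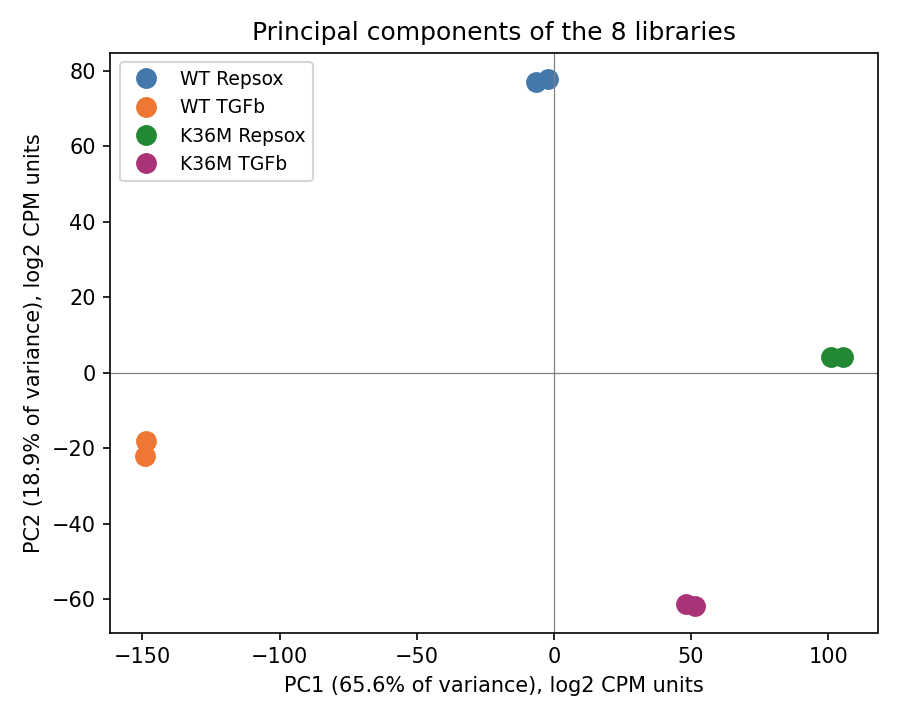
Principal components of log2 CPM over the tested genes, with the first component (65.6% of the variance) on x and the second (18.9%) on y, each point being 1 library coloured by group. WT under TGF-beta lies at about -149 on the first component and the K36M groups on the positive side.

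H3f3a and H3f3b encode the histone H3.3 protein, and a gene count cannot tell a mutant transcript from a normal one. H3f3a (chromosome 1, 182730963 to 182744074 on mm9) stood at 102 ± 0.628 CPM in WT under Repsox, 97.7 ± 3.5 in WT under TGF-beta, 56.9 ± 0.580 in K36M under Repsox and 87.3 ± 4.02 in K36M under TGF-beta. H3f3b (chromosome 11, 115883226 to 115889276) stood at 246 ± 0.887, 221 ± 0.217, 268 ± 1.69 and 321 ± 24.6 CPM in the same order. Whether a mutant copy was read as either gene was not recorded. The reprogramming factors, whose reads can come from the transgene or the endogenous gene, were read in every group: Pou5f1 at 398 ± 31.9, 425 ± 12.9, 207 ± 2.08 and 310 ± 2.13 CPM, and Sox2 at 277 ± 15.5, 313 ± 4.17, 178 ± 6.11 and 107 ± 7.24 CPM. Klf4 and Myc were 2.65-fold (log2 -1.40 ± 0.07) and 2.73-fold (log2 -1.45 ± 0.07) lower in K36M than in WT under Repsox, and 3.32-fold and 3.09-fold lower under TGF-beta.

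K36M was compared with WT under Repsox, while the TGF-beta receptor was inhibited (2 libraries each). Because the reprogramming factors also stood lower in K36M in both media, a genotype difference cannot be assigned to the mutant histone alone. In K36M, 31 of 34 tested mesenchymal and fibroblast genes were lower and 0 higher, with a median log2 fold change of -3.92. Thy1 (chromosome 9, 43851467 to 43856662), a surface glycoprotein of fibroblasts, was 38.4-fold lower, at 14.3 ± 0.590 against 551 ± 1.89 CPM (log2 -5.26 ± 0.10, adjusted p = 2.21e-20). Vim, the intermediate filament protein of mesenchymal cells, was 18.3-fold lower (log2 -4.19 ± 0.08, adjusted p = 1.43e-20), Col6a1, a collagen VI chain, 21.3-fold (log2 -4.41 ± 0.09) and Col1a1, the main fibrillar collagen of fibroblasts, 11.9-fold (log2 -3.57 ± 0.12). All 16 tested interferon response genes were higher, with a median of 3.11. Rsad2, the antiviral protein viperin, was 21.1-fold higher, at 164 ± 1.02 against 7.76 ± 0.182 CPM (log2 4.40 ± 0.12, adjusted p = 1.32e-17), Oasl2, an interferon-induced oligoadenylate synthetase relative, 17.1-fold (log2 4.10 ± 0.15) and Bst2, the virus tether tetherin, 3.29-fold (log2 1.72 ± 0.09). The camera test gave adjusted p = 5.78e-67 for the mesenchymal list and 6.5e-20 for the interferon list, and both passed with an estimated correlation (adjusted p = 0.0406 for each).

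Epithelial genes were higher as a group in K36M under Repsox, with 28 of 32 higher and 2 lower (median 1.13, camera adjusted p = 2.77e-15; adjusted p = 0.116 with an estimated correlation). Cdh1, the epithelial cadherin (chromosome 8, 109127251 to 109194146), was 2.02-fold higher (log2 1.01 ± 0.11), and the keratins Krt7 and Krt18 4.18-fold (log2 2.06 ± 0.10) and 2.75-fold (log2 1.46 ± 0.07). Of 14 trophoblast genes 11 were higher and 1 lower (median 1.43, adjusted p = 1.34e-09; adjusted p = 0.0992 with an estimated correlation), among them Hand1, a transcription factor of trophoblast giant cells, 5.45-fold (log2 2.45 ± 0.14) and Sfmbt2, an imprinted placental gene, 3.36-fold (log2 1.75 ± 0.09). Of 13 germline genes 11 were higher and 0 lower (median 3.69, or 3.39 with unread genes at their bound; adjusted p = 0.000213; adjusted p = 0.0992 with an estimated correlation), including Dazl, an RNA-binding protein of germ cells, at 7.92 ± 1.08 against 0.601 ± 0.103 CPM. Lower as groups were the p53 and senescence genes, 15 of 16 with 0 higher (median -0.77, adjusted p = 1.05e-06; adjusted p = 0.0666 with an estimated correlation), and the BMP and ID response genes, 10 of 13 with 1 higher (median -1.68, adjusted p = 0.000237; adjusted p = 0.0992 with an estimated correlation). The cell cycle inhibitors Cdkn1a and Cdkn2a were 2.98-fold (log2 -1.58 ± 0.06) and 3.87-fold (log2 -1.95 ± 0.11) lower, and the inhibitor of differentiation Id1 3.45-fold (log2 -1.79 ± 0.09).

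The TGF-beta response list held 7 genes higher and 13 lower of 22 in K36M under Repsox (median -0.53, adjusted p = 0.00105; adjusted p = 0.161 with an estimated correlation), and the pathway component list 6 higher and 9 lower of 17 (median -0.31, adjusted p = 0.000697; adjusted p = 0.109 with an estimated correlation). Ltbp2, a matrix protein that resembles the latent TGF-beta binding proteins, was 35.1-fold lower (log2 -5.13 ± 0.15), Ltbp1, which tethers latent TGF-beta in the matrix, 22.8-fold lower (log2 -4.51 ± 0.09) and the receptor gene Tgfbr2 5.00-fold lower (log2 -2.32 ± 0.10). Pluripotency genes did not pass as a list (18 higher and 6 lower of 30, adjusted p = 0.173; 0.0280 without WT Repsox library 1 and 0.0280 to 0.660 over all alternatives), and Nanog, a core pluripotency factor, stood at 104 ± 4.50 against 122 ± 11.2 CPM (log2 -0.23 ± 0.19, adjusted p = 0.314). Nanog was called lower under 4 of 18 alternatives (adjusted p 0.00850 to 0.809 over all).

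The largest single increases in K36M under Repsox were those of Sohlh2, a germ cell transcription factor, 79.7-fold (log2 6.32 ± 0.44), Oas3, an oligoadenylate synthetase, 64.6-fold (log2 6.01 ± 0.46), and the kallikrein Klk7, 44.9-fold (log2 5.49 ± 0.21), followed by Smc1b, Mlxipl, Trim63, Cntn1 and Ddx60 at 31.5 to 23.5-fold. Without WT Repsox library 1 the log2 value was 7.15 for Sohlh2, 9.99 for Oas3 and 7.44 for Smc1b. Without library 2 it was 5.14 for Oas3, 4.18 for Smc1b and 5.72 for Mlxipl. The decreases that were largest by fitted fold change, whose order depends on the prior count where a group had few or 0 counts, included Rps13-ps1, a ribosomal protein retrocopy at 26.5 ± 6.52 CPM in WT and 0 in K36M (at least 242-fold lower). Cdh11, the mesenchymal cadherin, was 172-fold lower (log2 -7.43 ± 0.18) and Tnc, the matrix protein tenascin C, 149-fold lower (log2 -7.22 ± 0.19). Inhba, which encodes a subunit of activin, was 99.1-fold lower (log2 -6.63 ± 0.32). Without K36M Repsox library 1 the log2 value was -6.52 for Tnc and -5.83 for Inhba. Without library 2 it was -8.14 for Cdh11, -8.30 for Tnc and -7.97 for Inhba. The chemokine gene Ccl7 was lower by a ratio of 319 (interval 56.8 to 12600), Pcdh18 by 200 (54.9 to 1650) and Has2, a hyaluronan synthase, by 155 (27.5 to 6180). Rpl34-ps1 was lower by a ratio of 156 (43.0 to 1300), and reads of retrocopies can be shared with their parent genes.

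Of 15789 genes tested with edgeR, 4551 were higher and 4254 lower in K36M under Repsox, and 1894 and 1964 of them by at least 2-fold. Adjusted over the list alone, the counts were 1 higher and 32 lower for mesenchymal genes, 12 and 1 for trophoblast, 13 and 0 for germline, 16 and 0 for interferon response, 28 and 2 for epithelial, 0 and 15 for p53, 1 and 10 for BMP and ID, 7 and 13 for TGF-beta response, 6 and 9 for pathway components, and 18 and 6 for pluripotency. The other 14 lists did not pass (adjusted p 0.173 to 0.732). Their higher and lower counts were 6 and 1 of 10 for endothelial, 5 and 0 of 9 for muscle, 13 and 3 of 22 for proliferation, 8 and 2 of 17 for H3K36 methylation machinery, 1 and 7 of 12 for neural, 6 and 3 of 12 for primitive endoderm, and 5 and 4 of 10 for cartilage and bone. They were 8 and 16 of 57 for replication-dependent histones, 8 and 3 of 19 for Polycomb components, 3 and 1 of 11 for keratinocyte, 2 and 0 of 3 for adipocyte, 2 and 3 of 6 for macrophage and blood, 7 and 7 of 17 for imprinted and 7 and 5 of 16 for contractile genes. Adjusted over the list alone these counts became 7 and 1 for endothelial, 2 and 7 for neural, 7 and 4 for primitive endoderm and 7 and 16 for histones, with the other 10 lists as given.

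Under TGF-beta, the comparison of K36M with WT (2 libraries each) asked how the mutant cells differed from WT cells when the pathway was stimulated. It includes differences already present under Repsox, such as the lower mesenchymal genes (median -3.92 there). Whether the response differed was tested by the interaction. Epithelial genes stood far higher in K36M, 31 of 32 with 1 lower and a median log2 fold change of 4.68. Krt18 (chromosome 15, 101858647 to 101862457), a keratin of simple epithelia, was 68.4-fold higher, at 727 ± 38.7 against 10.6 ± 1.42 CPM (log2 6.10 ± 0.10, adjusted p = 1.21e-21). Its partner Krt8 was 40.1-fold higher (log2 5.33 ± 0.09), Cdh1 35.2-fold (log2 5.14 ± 0.14) and the adhesion molecule Epcam 27.4-fold (log2 4.78 ± 0.17). Pluripotency genes were higher in 26 of 30 and lower in 3 (median 4.20, or 3.89 with unread genes at their bound). Tdgf1, the Nodal co-receptor Cripto, was 104-fold higher (log2 6.70 ± 0.15), Nanog 12.7-fold, at 104 ± 1.27 against 8.54 ± 7.52 CPM (log2 3.66 ± 0.25), and Sall4, a zinc finger factor of embryonic stem cells, 19.6-fold (log2 4.29 ± 0.11). Without WT TGF-beta library 1 the log2 value of Nanog was 5.00. Without library 2 it was 2.91, and that of Tdgf1 7.31. Camera gave adjusted p = 5.46e-45 for the epithelial and 8.08e-16 for the pluripotency list; with an estimated correlation, adjusted p = 0.0739 and 0.0903.

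Cell division genes were also higher in K36M under TGF-beta. Of 22 proliferation genes 20 were higher and 1 lower (median 2.45, adjusted p = 5.59e-20; adjusted p = 0.0121 with an estimated correlation), and of 57 replication-dependent histone genes 50 were higher and 3 lower (median 2.54, adjusted p = 1.96e-25; adjusted p = 0.0969 with an estimated correlation). Top2a, the topoisomerase of dividing cells, was 10.6-fold higher, at 794 ± 14.7 against 75.0 ± 4.45 CPM (log2 3.40 ± 0.07), and Mki67, the Ki-67 antigen, 8.47-fold (log2 3.08 ± 0.07). The linker histone genes Hist1h1e and Hist1h1d were 8.78-fold (log2 3.13 ± 0.08) and 9.32-fold (log2 3.22 ± 0.10) higher, with reads that near-identical histone copies may share. Trophoblast genes were higher in 11 of 14 with 0 lower (median 3.72, adjusted p = 4e-09; adjusted p = 0.0760 with an estimated correlation), led by Krt7, 254-fold (log2 7.99 ± 0.20), and Tfap2c, an AP-2 factor of trophoblast and germ cells, 36-fold (log2 5.17 ± 0.14). Imprinted genes were higher in 13 of 17 and lower in 2 (median 1.14, adjusted p = 0.000223; adjusted p = 0.0760 with an estimated correlation), with the growth factor gene Igf2 71.4-fold (log2 6.16 ± 0.23) and the non-coding H19 129-fold (log2 7.01 ± 0.26) higher. The 2 WT TGF-beta libraries differed widely for these genes. Without library 1 the log2 value was 5.51 for Igf2 and 6.39 for H19, and without library 2 it was 7.62, 8.29 and, for Krt7, 9.04.

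Mesenchymal and TGF-beta genes were lower in K36M under TGF-beta. Of 34 mesenchymal genes 28 were lower and 2 higher (median -2.94, adjusted p = 3.98e-26; adjusted p = 0.0760 with an estimated correlation). Vim was 15.7-fold lower (log2 -3.98 ± 0.08), Cdh2, the neural cadherin gained in mesenchymal transition, 38.5-fold (log2 -5.27 ± 0.12) and Col1a1 7.92-fold (log2 -2.98 ± 0.11). Thy1 was 1.30-fold higher in K36M (log2 0.38 ± 0.10, adjusted p = 0.00152; 0.0713 without WT TGF-beta library 1 and 1.93e-05 to 0.0713 over all alternatives), at 37.3 ± 0.849 against 28.5 ± 3.89 CPM. Of 22 TGF-beta response genes 17 were lower and 1 higher (median -1.77, adjusted p = 2.27e-12; adjusted p = 0.0739 with an estimated correlation): Ctgf, a matricellular growth factor, was 13.4-fold lower (log2 -3.75 ± 0.09) and Smad7, the inhibitory Smad, 3.48-fold (log2 -1.80 ± 0.08). Of 16 contractile genes 12 were lower and 2 higher (median -0.91, adjusted p = 1.53e-05; adjusted p = 0.145 with an estimated correlation), including the smooth muscle actin gene Acta2, 7.99-fold lower (log2 -3.00 ± 0.09).

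Pathway components (5 higher and 11 lower of 17, adjusted p = 0.00554), interferon response genes (12 and 1 of 16, adjusted p = 0.00627) and neural genes (3 and 7 of 12, adjusted p = 0.0122) also passed under TGF-beta. Polycomb components (12 and 5 of 19, adjusted p = 0.0358) and endothelial genes (7 and 2 of 10, median 3.45, or 3.08 with unread genes at their bound, adjusted p = 0.0433) passed as well. With an estimated correlation these 5 lists had adjusted p = 0.118, 0.145, 0.145, 0.145 and 0.145. Among Polycomb genes, Jarid2 and Cbx7 were 5.68-fold (log2 2.51 ± 0.08) and 14.6-fold (log2 3.87 ± 0.14) higher, and the methyltransferase gene Ezh2 2.48-fold (log2 1.31 ± 0.09). The list did not pass without WT TGF-beta library 1 (adjusted p = 0.0529; 0.0140 to 0.145 over all alternatives). Dnmt3b, a DNA methyltransferase that binds methylated H3K36, was 23.2-fold higher (log2 4.54 ± 0.13), although the H3K36 methylation list as such did not pass (10 higher and 4 lower of 17, adjusted p = 0.193).

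The genes with the largest fitted increases under TGF-beta, in an order that depends on the prior count, had 0 counts in both WT libraries: Aire, the autoimmune regulator (at least 306-fold), the Wnt ligand gene Wnt6 (at least 191-fold), Hrc (at least 144-fold), Ybx2 (at least 108-fold), Myl3 (at least 99.8-fold), Tie1 (at least 88.9-fold), Trim63 (at least 88.2-fold) and Bst1 (at least 82.9-fold). Aire stood at 36 ± 0.975 CPM in K36M. Among the largest fitted decreases, Rps13-ps1 (at least 166-fold) and Adamtsl3 (at least 56.0-fold) had 0 counts in K36M. Megf10 (log2 -8.02 ± 0.16) and Igfbp5, an insulin-like growth factor binding protein (log2 -7.88 ± 0.14), were 259-fold and 236-fold lower. Frem1, Cdh6 and Tll1 were 296, 206 and 148-fold lower. Frem1 and Cdh6 had log2 values of -12.97 and -6.63 without K36M TGF-beta library 1, and of -7.30 and -12.69 without library 2. Slc2a13 was lower by a ratio of 257 (interval 45.8 to 10200).

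In all, 5741 genes were higher and 5357 lower in K36M under TGF-beta, and 3542 and 2648 of them by at least 2-fold. Adjusted over the list alone, the counts of the lists that passed were as given, except 2 higher and 17 lower for TGF-beta response. The other 10 lists did not pass (adjusted p 0.0644 to 0.949), the germline list (11 higher and 0 lower of 13, or 12 and 0 adjusted over the list alone) being nearest. It passed under 1 of 12 alternatives (adjusted p 0.0353 to 0.198). The median of all genes was 0.051 with TMM, 0.174 with upper-quartile and 0.248 with library-size scaling, and the share of higher calls 51.7% with TMM, 57.6% with upper-quartile factors and 61.0% with library sizes.

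**Figure D2:**
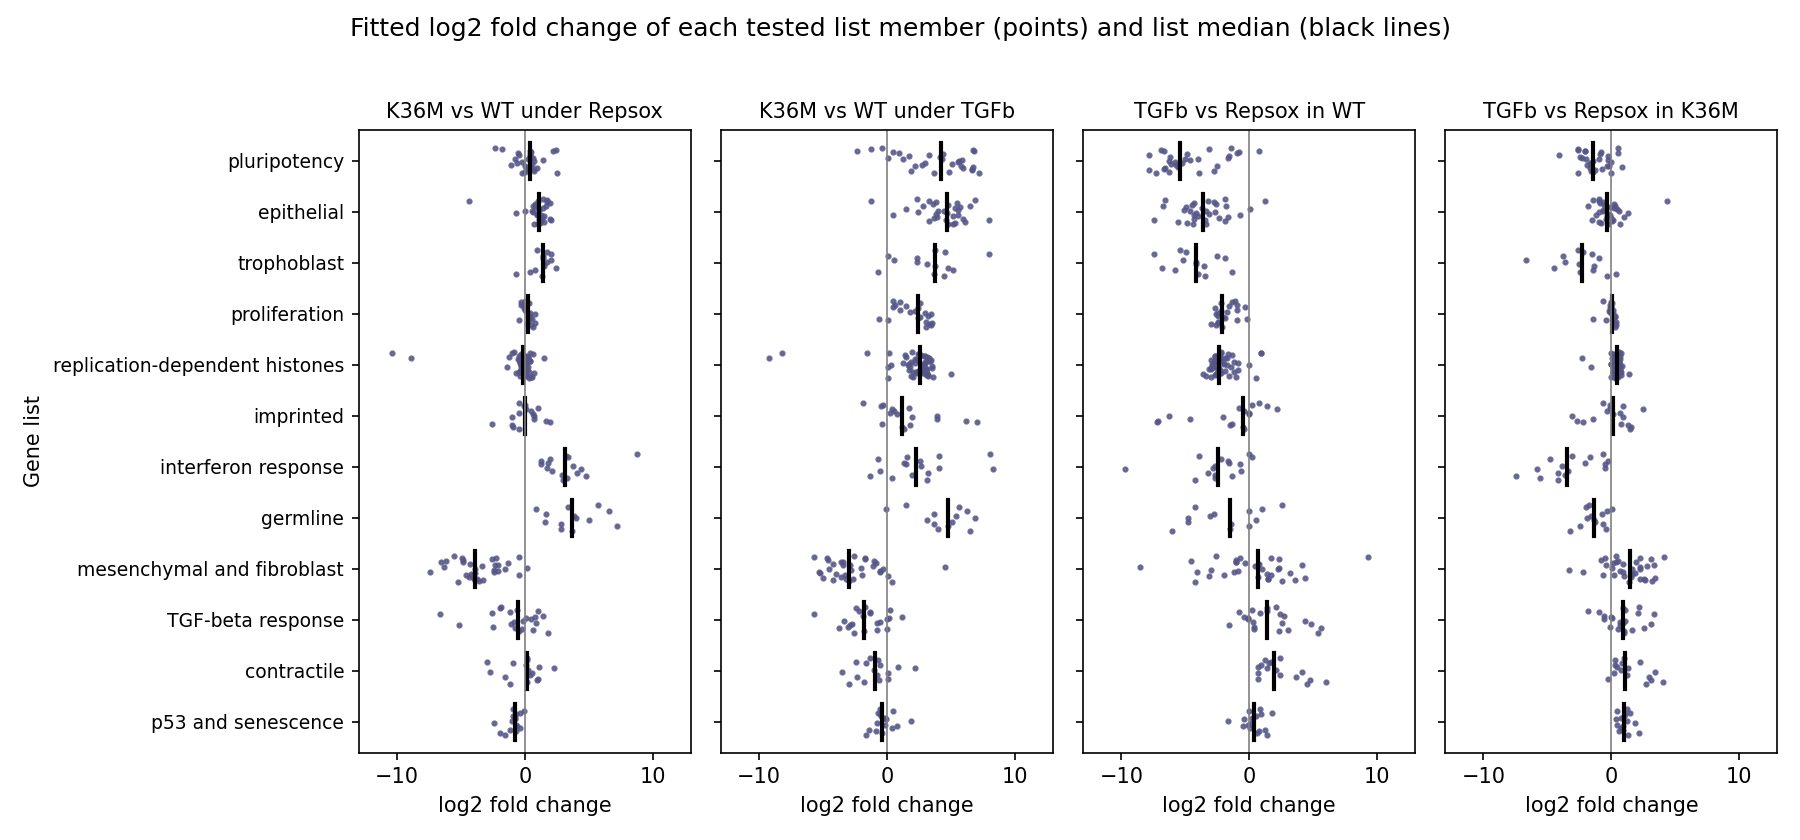
Fitted log2 fold change (x) of each tested member of 12 gene lists (y) in the 4 pairwise comparisons, with a point per gene, a black line at the median of the list and a grey line at 0. Epithelial medians lie at 1.13 and 4.68 for K36M against WT under Repsox and TGF-beta, and at -3.58 and -0.32 for TGF-beta against Repsox in WT and K36M.

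TGF-beta and Repsox were compared in WT cells (2 libraries each) to ask what the pathway did to normal intermediates. Known targets of TGF-beta rose: Ctgf (chromosome 10, 24315248 to 24318489) by 48.2-fold, from 43.1 ± 3.37 to 2080 ± 32.8 CPM (log2 5.59 ± 0.10, adjusted p = 1.6e-21), Pmepa1, a negative feedback regulator of the pathway, by 28.4-fold (log2 4.83 ± 0.12) and Smad7 by 5.03-fold (log2 2.33 ± 0.08). All 16 contractile genes rose, with Tagln, the actin-binding protein transgelin, 63.6-fold (log2 5.99 ± 0.10) and Acta2 23.3-fold (log2 4.54 ± 0.10) higher. Of 30 pluripotency genes 29 fell and 1 rose (median -5.40, or -5.11 with unread genes at their bound). Nanog fell 14.9-fold (log2 -3.89 ± 0.25), Sall4 32.3-fold (log2 -5.01 ± 0.11) and Esrrb, an orphan receptor of naive stem cells, 75.9-fold (log2 -6.25 ± 0.15). Nanog had a log2 value of -5.23 without WT TGF-beta library 1 and of -3.14 without library 2. Camera gave adjusted p = 8.49e-17 for the TGF-beta response (16 higher and 3 lower of 22, median 1.38), 5.01e-21 for contractile genes (median 1.91) and 8.02e-34 for pluripotency. With an estimated correlation these were adjusted p = 0.0385, 0.0533 and 0.0533.

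Epithelial, trophoblast and cell division genes fell in WT under TGF-beta. Of 32 epithelial genes 30 fell and 1 rose (median -3.58, adjusted p = 6.54e-35; adjusted p = 0.0547 with an estimated correlation), Krt18 by 48.5-fold (log2 -5.60 ± 0.10) and Cdh1 by 21.2-fold, from 673 ± 9.65 to 32.1 ± 12.7 CPM (log2 -4.41 ± 0.14). All 14 trophoblast genes fell (median -4.17, adjusted p = 1.31e-19; adjusted p = 0.0390 with an estimated correlation), Peg10, an imprinted placental gene derived from a retrotransposon, by 41.6-fold (log2 -5.38 ± 0.11). Of 22 proliferation genes 21 fell and 0 rose (median -2.11, adjusted p = 7.14e-21; adjusted p = 0.0111 with an estimated correlation), Top2a by 6.01-fold (log2 -2.59 ± 0.07). Of 57 replication-dependent histone genes 52 fell and 2 rose (median -2.34, adjusted p = 4.55e-25; adjusted p = 0.0998 with an estimated correlation), Hist1h1a by 10.5-fold (log2 -3.39 ± 0.11). The 2 libraries of WT under TGF-beta differed widely in some of the genes that fell, with Nanog at 8.54 ± 7.52 CPM and Igf2 at 8.23 ± 7.25. Imprinted genes fell in 11 of 17 and rose in 3 (median -0.52, adjusted p = 0.00077; adjusted p = 0.0583 with an estimated correlation). Igf2 fell 143-fold (log2 -7.16 ± 0.23; -6.52 without WT TGF-beta library 1 and -8.63 without library 2) and Cdkn1c, an imprinted cell cycle inhibitor, 79.6-fold (log2 -6.31 ± 0.14).

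The mesenchymal list was divided in WT, with 17 genes higher and 14 lower of 34 (median 0.69, adjusted p = 0.000785; adjusted p = 0.313 with an estimated correlation). Col5a2, a fibrillar collagen chain, rose 20.8-fold (log2 4.38 ± 0.10), Fbln2, the matrix protein fibulin, 17.6-fold (log2 4.13 ± 0.08) and Col1a1 6.05-fold (log2 2.60 ± 0.11), whereas Thy1 fell 19.3-fold (log2 -4.27 ± 0.09). Interferon response genes fell in 12 of 16 with 0 higher (median -2.43, adjusted p = 0.000785; adjusted p = 0.154 with an estimated correlation). BMP and ID response genes fell in 10 of 13 and rose in 2 (adjusted p = 0.0402; adjusted p = 0.195 with an estimated correlation), Id2 by 8.69-fold (log2 -3.12 ± 0.15), while the BMP antagonist Bmper rose 37.0-fold (log2 5.21 ± 0.18). Polycomb components fell in 12 of 19 and rose in 4 (adjusted p = 0.00536; adjusted p = 0.0998 with an estimated correlation). Neural genes (5 higher and 3 lower of 12, adjusted p = 0.00368) and p53 genes (9 and 3 of 16, adjusted p = 0.0204) had adjusted p = 0.163 and 0.164 with an estimated correlation.

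The largest fitted increase in WT was that of Lox (chromosome 18, 52675723 to 52689521), the enzyme that crosslinks collagen, which rose 629-fold from 4.14 ± 0.624 to 2630 ± 37.2 CPM (log2 9.30 ± 0.25, adjusted p = 1.06e-18). C1qtnf3, Fbxo40, Megf10, Cpn1 and Fermt1 rose 598, 431, 391, 250 and 195-fold. Without WT Repsox library 1 the log2 value was 8.56 for C1qtnf3, 12.72 for Fbxo40 and 9.21 for Megf10. Without library 2 it was 10.28 for C1qtnf3 and 7.87 for Fbxo40. The lymphoid factor gene Ikzf1 rose by a ratio of 287 (interval 97.9 to 1400) and Alpk2 by 214 (58.8 to 1770). Of the 8 genes with the largest fitted decreases, in an order that depends on the prior count, 7 had 0 counts under TGF-beta: Foxd3, a factor of stem cells and neural crest (at least 91.9-fold), Rsad2 (at least 66.1-fold), Lrrc34 (at least 60.1-fold), Trap1a (at least 57.9-fold), Aire (at least 57.3-fold), the secretin gene Sct (at least 49.4-fold) and Dmrt1, a gonadal sex factor (at least 34.9-fold). Igf2as fell by a ratio of 944 (interval 169 to 37300), with reads that may come from the overlapping Igf2.

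In all, 4580 genes were higher and 5271 lower under TGF-beta in WT, and 1940 and 2887 of them by at least 2-fold. Higher calls were 46.5% of the total with TMM and 33.8% with library-size scaling, and the median of all genes moved from -0.068 with TMM to -0.128 with upper-quartile factors and -0.275 with library sizes. Adjusted over the list alone, the counts of the lists that passed were as given, except 17 higher and 15 lower for mesenchymal and 4 and 13 for Polycomb genes. The other 10 lists did not pass (adjusted p 0.108 to 0.767). Pou5f1 stood at 425 ± 12.9 against 398 ± 31.9 CPM (log2 0.10 ± 0.07, adjusted p = 0.233). It was called only without WT Repsox library 1 (log2 0.18, adjusted p = 0.0211; log2 -0.11 to 0.18 and adjusted p 0.0211 to 0.857 over all 18 alternatives). Sox2 was 1.13-fold higher (log2 0.18 ± 0.07, adjusted p = 0.0445), a call lost or turned under 11 of 18 alternatives (adjusted p 0.00787 to 0.718), with library-size scaling giving log2 -0.03.

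The same treatments were compared in K36M cells (2 libraries each) to ask how the pathway acted when the mutant histone was present. Trophoblast genes fell in 12 of 14 with 0 higher (median -2.32) and interferon response genes in 14 of 16 with 0 higher (median -3.49). Hand1 (chromosome 11, 57642207 to 57646320) fell 22.2-fold, from 78.8 ± 6.09 to 3.49 ± 1.36 CPM (log2 -4.47 ± 0.17, adjusted p = 2.81e-15), Gata2, a zinc finger factor of trophoblast and blood, 14.1-fold (log2 -3.81 ± 0.11) and Rsad2 55.0-fold (log2 -5.78 ± 0.14). All 16 p53 and senescence genes rose (median 0.97), Cdkn2a by 4.41-fold (log2 2.14 ± 0.11) and Cdkn1a by 2.42-fold (log2 1.28 ± 0.06). Camera gave adjusted p = 6.9e-25 for trophoblast, 2.14e-24 for interferon and 3.28e-11 for p53 genes, and each passed with an estimated correlation (adjusted p = 0.0316 for all 3).

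Contractile genes rose in 14 of 16 and fell in 1 in K36M (median 1.10, adjusted p = 1.03e-13; adjusted p = 0.0643 with an estimated correlation), Tagln by 16.2-fold (log2 4.01 ± 0.09). Mesenchymal genes rose in 22 of 34 and fell in 5 (median 1.45, adjusted p = 4.55e-15; adjusted p = 0.121 with an estimated correlation). Col1a1 rose 9.10-fold, from 33.4 ± 6.10 to 303 ± 5.29 CPM (log2 3.19 ± 0.12), and Fstl1, a secreted glycoprotein, 8.70-fold (log2 3.12 ± 0.07). TGF-beta response genes rose in 15 of 22 and fell in 4 (median 0.92, adjusted p = 7.33e-08; adjusted p = 0.0652 with an estimated correlation), Ctgf by 6.03-fold (log2 2.59 ± 0.09) and Smad7 by 2.03-fold (log2 1.02 ± 0.09). Pluripotency genes fell in 24 of 30 and rose in 3 (median -1.44, adjusted p = 6.42e-12; adjusted p = 0.121 with an estimated correlation), including Klf2, a factor of the naive state, by 5.58-fold (log2 -2.48 ± 0.14). Nanog stood at 104 ± 1.27 against 104 ± 4.50 CPM (log2 0.01 ± 0.19, adjusted p = 0.987).

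Epithelial genes were mixed in K36M, with 7 higher and 16 lower of 32 (median -0.32, adjusted p = 0.0216; adjusted p = 0.517 with an estimated correlation, 0.0649 without K36M TGF-beta library 2, and 0.0105 to 0.517 over all alternatives). Cdh1 stood at 1120 ± 12.6 against 1360 ± 35.6 CPM (log2 -0.28 ± 0.11, adjusted p = 0.0428; 0.503 with DESeq2 and 8e-07 to 0.503 over all alternatives). Histone genes rose in 34 of 57 with 0 lower (median 0.43, adjusted p = 0.000477; adjusted p = 0.430 with an estimated correlation). Proliferation genes did not pass (6 higher and 3 lower of 22, adjusted p = 0.894). Adipocyte genes fell in 3 of 3 (adjusted p = 0.000496), keratinocyte genes rose in 4 of 11 and fell in 1 (adjusted p = 0.0132), and germline genes fell in 8 of 13 with 0 higher (adjusted p = 0.0227). With an estimated correlation these 3 lists had adjusted p = 0.0911, 0.121 and 0.231. Krt17, a keratin of basal and stressed epithelia, rose 11.4-fold (log2 3.51 ± 0.20).

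Among the largest fitted increases in K36M, whose order depends on the prior count, was that of Lefty2 (chromosome 1, 182823239 to 182829234), a secreted Nodal antagonist, which rose 660-fold from 0.227 ± 0.134 to 150 ± 17.1 CPM (log2 9.37 ± 0.31, adjusted p = 3.45e-16; log2 10.05 without K36M Repsox library 2). Lefty1 rose 61.9-fold (log2 5.95 ± 0.28) and Chst15, a sulfotransferase gene, 58.2-fold (log2 5.86 ± 0.18). Trim67, Has2 and Myoz2 rose by ratios of 718 (interval 128 to 28400), 223 (39.6 to 8870) and 106 (18.6 to 4230), and Gabra2 at least 30.4-fold. Dmrtc1a fell at least 209-fold, Slc14a1 at least 6.14-fold, and the kallikrein Klk7 361-fold (log2 -8.50 ± 0.31). The fitted log2 value of Slc14a1 was -6.33, and -5.1 without K36M Repsox library 1. Pparg, the master regulator of adipocytes, fell by a ratio of 290 (interval 80.0 to 2400), Klk6 by 484 (86.6 to 19200) and Serpinb9e by 345 (61.5 to 13700). The placental gene Plac1 and the transporter gene Slc38a8 fell 102-fold and 79.3-fold. Without K36M TGF-beta library 1 the log2 value was -7.86 for Klk7 and -8 for Plac1, and without library 2 it was -9.49 and -6.05.

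In all, 3895 genes were higher and 3731 lower under TGF-beta in K36M, and 1696 and 1302 of them by at least 2-fold. Adjusted over the list alone, the counts of the lists that passed were as given, except 3 higher and 25 lower for pluripotency and 35 and 0 for histones. The other 12 lists did not pass (adjusted p 0.0665 to 0.899). Of these, the muscle list (adjusted p = 0.0665) passed under 5 of 12 alternatives (0.0340 to 0.228 over all). The H3K36 methylation list (adjusted p = 0.141) passed under 2 (0.0388 to 0.430).

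**Figure D3:**
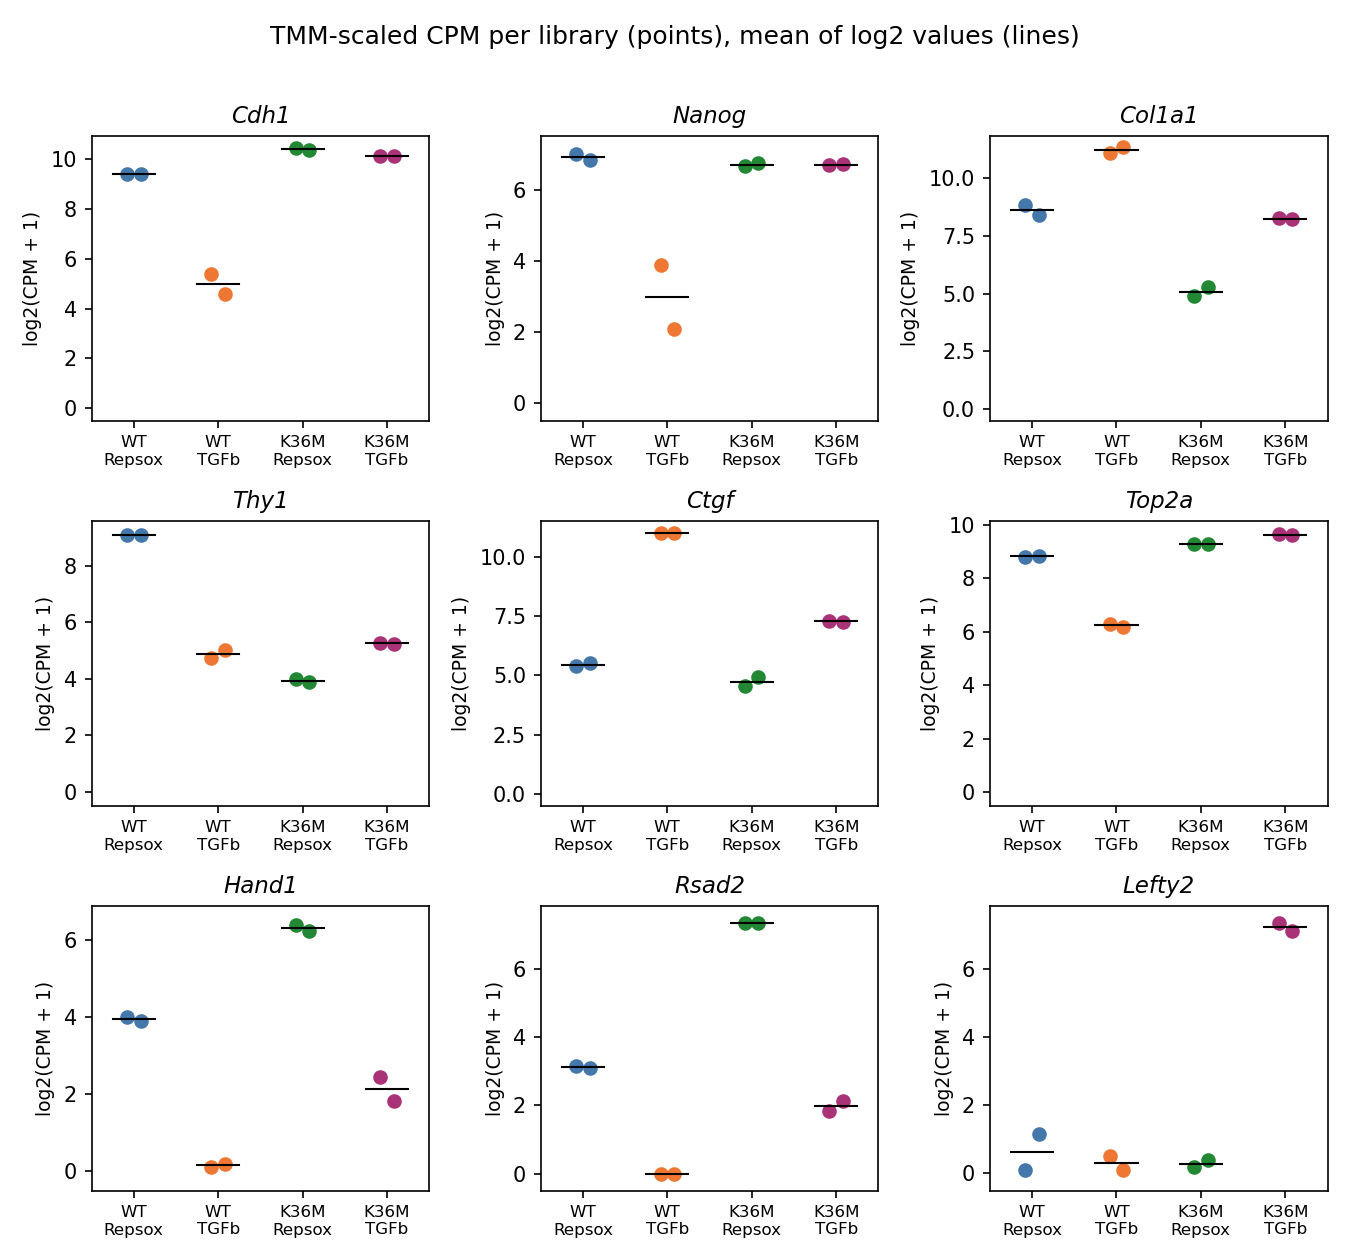
Levels of 9 genes as log2(CPM + 1) on y in the 4 groups on x, with a point per library and a line at the mean of the 2 log2 values. Cdh1 and Nanog are low in WT under TGF-beta, at 32.1 and 8.54 CPM, and stand at 1120 and 104 CPM in K36M under TGF-beta.

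Whether the medium acted differently in the 2 genotypes was tested by the interaction, positive where the change from Repsox to TGF-beta was higher in K36M than in WT. Epithelial genes had a positive interaction in 30 of 32 and a negative one in 1 (median 3.77), and pluripotency genes in 26 and 2 of 30 (median 3.94). The interaction was 4.63 ± 0.12 for Krt18 (adjusted p = 1.58e-17), 4.13 ± 0.17 for Cdh1, 6.41 ± 0.19 for Tdgf1 and 3.90 ± 0.32 for Nanog, on the log2 scale with 2 libraries per group. Without WT TGF-beta library 1 it was 5.23 for Nanog. Without library 2 it was 3.14 for Nanog and 7.02 for Tdgf1. Proliferation genes were positive in 21 of 22 and negative in 1 (median 2.15), with Top2a at 2.94 ± 0.09, and histone genes in 50 of 57 with 0 negative (median 2.83), with Hist1h1e at 3.21 ± 0.11. TGF-beta response genes were positive in 5 and negative in 12 of 22 (median -0.48). This median was -0.37 with upper-quartile factors and -0.26 with library sizes. Ctgf had an interaction of -3.00 ± 0.13 and Smad7 of -1.31 ± 0.12. Thy1, which fell in WT and rose in K36M, had an interaction of 5.65 ± 0.14.

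Camera gave the interaction adjusted p = 5.77e-43 for epithelial, 7.95e-24 for pluripotency, 1.03e-25 for proliferation, 1.33e-43 for histone and 1.7e-06 for TGF-beta response genes. The proliferation list passed with an estimated correlation (adjusted p = 0.00717) and the other 4 did not (adjusted p = 0.0608 for each). The preset correlation also called imprinted genes (12 positive and 1 negative of 17, median 1.83, adjusted p = 3.15e-06), trophoblast genes (9 and 1 of 14, median 2.29, adjusted p = 1.54e-05) and contractile genes (0 and 12 of 16, median -0.83, adjusted p = 2.75e-05). These 3 lists had adjusted p = 0.0608, 0.141 and 0.240 with an estimated correlation. Peg3, an imprinted zinc finger gene, had an interaction of 3.25 ± 0.09, Tfap2c of 4.40 ± 0.17 and Tagln of -1.97 ± 0.14. Adjusted over the list alone, the counts were 31 positive and 1 negative for epithelial, 10 and 1 for trophoblast, 1 and 12 for contractile genes, and as given for the other 5 lists that passed. The other 16 lists did not pass (adjusted p 0.0818 to 0.944). Of 12 alternatives, the p53 list passed under 6 (0.0130 to 0.240 over all) and the endothelial list under 3 (0.0358 to 0.240). The Polycomb (0.0231 to 0.240) and mesenchymal lists (0.0473 to 0.655) passed under 1 each.

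In all, 4493 genes had a positive and 3562 a negative interaction, and 2781 and 1450 of them by at least 2-fold. Positive calls were 55.8% of the total with TMM and 69.8% with library-size scaling, and the median of all genes moved from 0.093 with TMM to 0.211 with upper-quartile factors and 0.314 with library sizes. The largest fitted interactions were those of Lefty2 (10.70 ± 1.15) and Trim67 (9.53 ± 1.27), and among genes with 0 counts in 1 group, whose value depends on the prior count, those of Aire, Tie1 and Hrc. The most negative were those of Cpn1 (-7.82 ± 0.43), Megf10 (-6.54 ± 0.84), Fbxo40 (-6.34 ± 1.29), C1qtnf3 (-6.31 ± 0.89) and Dmrtc1a. These values moved when 1 library was left out: Lefty2 from 7.70 (WT Repsox library 2) to 12.28 (WT TGF-beta library 1), and Trim67 from 8.18 (WT Repsox library 2) to 11.81 (K36M Repsox library 2). Tie1 ran from 7.80 (WT Repsox library 2) to 9.88 (library 1). C1qtnf3 ran from -7.36 (WT Repsox library 2) to -4.66 (K36M Repsox library 2). Without WT Repsox library 1 Megf10 stood at -7.14 and Fbxo40 at -10.32. Fbxo40 did not pass without K36M Repsox library 2 (log2 -4.75, adjusted p = 0.127; 1.17e-07 to 0.127 over all alternatives).

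The genotype differences were compared between media, which share no library. Of 15789 genes, 2953 were higher in K36M in both media, where independent lists would share 1655, and 2771 were lower in both, against 1443. In opposite directions were 657 higher under Repsox and lower under TGF-beta, and 628 the reverse. Across genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.61 and Spearman's rho = 0.57. The medium differences in the 2 genotypes shared 1854 higher genes, against 1130 for independent lists, and 1882 lower genes, against 1246, with 748 and 986 in opposite directions (r = 0.42, rho = 0.32).

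The K36M difference under Repsox was then set against the TGF-beta difference in WT, gene by gene. Computed from different libraries, so that no WT Repsox library entered both, the covariance of the log2 fold changes was -0.324 and -0.330 for the 2 ways to divide the replicates (r = -0.179 and -0.178). Pooled over replicates with the WT Repsox libraries shared, it was -0.278 (r = -0.160), where 50 simulated draws with no effect gave means of 0.035 (r = 0.499). Cdh1 and Krt18 were higher in K36M and fell under TGF-beta. Thy1 was lower in both comparisons.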

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

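The tests of a mixture of cell states, of genetic background and of macrophage transcripts were chosen after the results were seen. The following results stood out because the difference between TGF-beta and Repsox was not the same in WT and K36M cells, by the test of the interaction. It was positive for 4493 genes and negative for 3562. Lefty2 (10.70), Trim67 (9.53), Aire (9.37), Tie1 (9.17) and Hrc (8.83) had the largest positive values on the log2 scale. Cpn1 (-7.82), Megf10 (-6.54), Fbxo40 (-6.34), C1qtnf3 (-6.31) and Dmrtc1a (-6.29) had the largest negative ones. Aire, Tie1 and Hrc had 0 counts in WT under TGF-beta and Dmrtc1a 0 in K36M under TGF-beta, so that these values depend on the prior count. Leaving out 1 library gave 7.70 (WT Repsox library 2) to 12.28 (WT TGF-beta library 1) for Lefty2, 8.18 (WT Repsox library 2) to 11.81 (K36M Repsox library 2) for Trim67 and -10.32 (WT Repsox library 1) to -4.75 (K36M Repsox library 2) for Fbxo40. The medians of the lists that passed were 3.77 for epithelial, 3.94 for pluripotency, 2.15 for proliferation, 2.83 for replication-dependent histone, 2.29 for trophoblast, 1.83 for imprinted, -0.48 for TGF-beta response (-0.26 with library sizes alone) and -0.83 for contractile genes. With an estimated correlation only the proliferation list passed (adjusted p = 0.00717), and the other 7 had adjusted p of 0.0608 to 0.240.

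The first pattern weighed was the pluripotency genes, which fell under TGF-beta by a median of 5.40 on the log2 scale in WT and by 1.44 in K36M. Scaling between libraries was argued against, since the median interaction over 4 scalings was 3.91 at lowest and 4.16 at highest. The choice among them had little room to move it, since the median of all genes ran only from 0.067 with RLE to 0.314 with library sizes. These scalings are all relative to the other genes, so a change in total RNA per cell was not addressed. Depth was argued against likewise, since the median was 4.04 with every library thinned to 10928302 counts (SD of the median over resampled genes 0.382). The totals differed little, so thinning had little room to move it. A blend of the states seen in WT under TGF-beta and K36M under Repsox was argued against because 4.66% of tested genes in K36M under TGF-beta lay at least 2-fold beyond both, 529 above and 206 below. A simulated blend, with 14.7% of the WT state as the best-fitting share, gave 0.01%. A difference in how the 2 genotypes respond to the pathway stays as a hypothesis, since cells that differ in pace or composition in other ways were not tested. Nor were the lower levels of the reprogramming factors in K36M tested as a cause.

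The second pattern was a set of 41 genes read in both media in 1 genotype (at least 1 CPM) and near 0 in the other (at most 3 counts over 4 libraries). Of them, 22 were near 0 in K36M and 19 near 0 in WT. Rps13-ps1 had 26.5 and 20.6 CPM in WT and 0 in K36M, and H2-Q2, a class I histocompatibility gene, 0 in WT and 1.96 and 2.08 CPM in K36M. Both genes were singled out after their values were seen. Both are annotated as protein coding, so neither is among the 5 pseudogenes of the set. They do not represent the set as a whole. Other members, also picked after their values were seen, were Osr1, Angpt1 and Tnfsf11, near 0 in K36M. Stra8, Slfn4 and Ifi27l2a, a member of the interferon list, were near 0 in WT. Pseudogenes made up 12.2% of the set and 4% of 820 genes matched for level (Fisher's exact test, two-sided p = 0.0298). The matched genes were all read at 1 CPM or more in both genotypes and both media, a condition that may itself lower their share of pseudogenes. The test therefore cannot decide whether sequence differences between the backgrounds of the WT and K36M cells account for part of the set. A loss of expression that follows the cell state was left open. Of the set, 26.8% changed 2-fold between media, and of the matched genes 41.2% (Fisher's exact test, two-sided p = 0.0739). All matched genes were matched and scored in WT, but the 19 genes near 0 in WT were scored in K36M. Fewer genes differed 2-fold in K36M (1696 higher and 1302 lower, against 1940 and 2887 in WT), so the 2 shares cannot decide.

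The third pattern was the interferon response list, higher in all 16 genes in K36M under Repsox. Blood or macrophage cells were argued against: Lyz2, C1qa, C1qb, Tyrobp and Fcer1g, which macrophages make in large amounts, summed to 17 counts in K36M and 172 in WT under Repsox, a ratio of 0.100 with an exact interval of 0.0572 to 0.166. This sum replaced a first test, the count of members of the fixed macrophage and blood list called higher, which could not decide: Csf1r and Cd68 were higher in K36M (4.52-fold and 2.43-fold), 2 of the 6 tested members, while Laptm5, the most abundant, stood at 82.1 against 115 CPM. Interferon made by the cells is a candidate source, since the 6 interferon genes found among the deposited counts had 46 counts in K36M under Repsox and 4 in WT (ratio 11.7, interval 4.27 to 44.7). These were Ifnk, Ifnz, Ifnab, Ifna2, Ifna6 and Ifna13. Ifnb1 and Ifng had no entry and could not be read. All 46 came from Ifnk, with 23 in each library, so the source rests on 1 gene at a low count. Under TGF-beta the same 6 genes had 7 counts in each genotype, so these counts show no such source there. Yet 12 of 16 genes of the list were still higher in K36M (median 2.29, camera adjusted p = 0.00627, and adjusted p = 0.145 with an estimated correlation). Genetic background was not tested for this list. Its member Ifi27l2a was among the 41 genes of the second pattern, with 0 counts in WT in both media and 113 (Repsox) and 63 (TGF-beta) in K36M.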

How the results depend on the processing

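The thinning to equal totals was the alternative chosen after the main results were seen, before its own result was. In the 10 counts of calls, every alternative except a minimum fold stayed within 1.5 times the value reported; with library sizes alone the negative interaction count fell from 3562 to 2482. The 2 counts of shared calls did so under the alternatives run for them, which left out upper-quartile and library-size scaling, the other filters, the 4 libraries alone and the most abundant genes. With a log2 fold change of at least 1, the higher and lower counts were 1894 and 1964 for K36M against WT under Repsox, 3542 and 2648 under TGF-beta, 1940 and 2887 for TGF-beta against Repsox in WT, 1696 and 1302 in K36M, and 2781 and 1450 for the interaction, by construction of the stricter threshold. The covariance of -0.327 between the K36M and medium differences was -0.311 with library-size scaling, -0.339 with the CPM filter and -0.230 with libraries of the same replicate number for both differences. The last puts 1 WT Repsox library into both differences, which raises the covariance; the cause of the other 2 moves was not tested. Of 120 list results 57 passed, and 10 with an estimated correlation; the cause was not tested. Leaving out 1 library at a time gave 56 to 63; the lone library left in a group was assumed to vary like the others. Of 483 results on named genes, 21 changed their side of the threshold or direction under some alternative. Sox2 in WT reversed, from 0.18 to -0.03 with library sizes alone. Scaling turned the median of 2 of 120 lists, none of which passed, and in 14 lists, none passing, the median, mean and test differed in sign. Epcam lost its call with DESeq2 under Repsox (adjusted p = 0.0966; 2.37e-14 to 0.0966 over all alternatives) and in K36M (0.11; 1.45e-15 to 0.11), and Cdh1 in K36M lost its call under 8 settings. The replicate numbers did not pair the libraries (correlations of deviations -0.02 to 0.03); with the replicate block 4594 genes were higher in K36M under Repsox, against 4551, and the p53 list passed for the interaction (adjusted p = 0.0294, against 0.0818), as in 5 of the other alternatives (0.0130 to 0.240 over all 12). Thinned to 10928302 counts, the interaction had 4395 positive and 3368 negative genes. Which genes lost their call was not recorded. For genes near 0 only bounds or wide intervals are given where a group had at most 3 counts.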

Other observations

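The genes and families described here were singled out after their values were seen. In K36M under TGF-beta, 6 genes linked to Nodal, Wnt and the primitive streak had higher means than in the other 3 groups; no list of such genes was tested, and the Wnt family did not pass for TGF-beta against Repsox in K36M (adjusted p = 0.129). Nodal, the TGF-beta family ligand that patterns the early embryo, stood at 60.5 ± 1.85 CPM, against 18.1 ± 3.90 in K36M under Repsox, 0.510 ± 0.00981 in WT under TGF-beta and 18.7 ± 0.158 in WT under Repsox. Its antagonists Lefty2 and Lefty1 stood at 150 ± 17.1 and 43.2 ± 5.58 CPM, where the highest mean in the other groups was 0.638 and 5.39 CPM. The Wnt genes Wnt3 and Wnt8a stood at 16 ± 0.0758 and 47.1 ± 0.507 CPM, against 2.11 and 11.7 CPM at most elsewhere, and T, the brachyury gene of the streak, at 5.33 ± 0.746 CPM against 1.26 at most. Each of these genes was called at least 2-fold above both WT under TGF-beta and K36M under Repsox by edgeR, with 2 libraries per group. These calls rest on the values by which the genes were picked, so they are no separate support for a shared program. The difference from WT under Repsox was not tested.

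Krt17 and Krt5, keratins of basal epithelia, stood at 48.8 ± 1.92 and 11.0 ± 2.11 CPM in K36M under TGF-beta, against 4.21 and 1.32 CPM at most elsewhere. The fixed keratinocyte list did not pass for K36M against WT under TGF-beta (5 higher and 4 lower of 11, adjusted p = 0.365), and for TGF-beta against Repsox in K36M it passed with the preset correlation (4 higher and 1 lower, adjusted p = 0.0132) but not with an estimated one (adjusted p = 0.121).

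Of 230 families of genes with a shared symbol prefix, the collagens were lower in K36M under Repsox (21 lower and 7 higher of 40, camera adjusted p = 6.45e-13), as were the Hoxa (10 lower and 1 higher of 11, adjusted p = 0.0288) and Hoxc genes (7 lower and 0 higher of 8, adjusted p = 0.0075), which specify position along the body. None of the 3 passed with an estimated correlation (adjusted p = 0.883 for each). The Oas genes, interferon-induced synthetases, were higher in 8 of 8 (adjusted p = 0.00377) and the kallikrein genes in 7 of 9 with 0 lower (adjusted p = 0.00514), and neither passed with an estimated correlation (adjusted p = 0.883). For the interaction, the Mcm genes of the replicative helicase were positive in 10 of 10 (adjusted p = 3.39e-07) and the annexin genes negative in 9 of 11 with 0 positive (adjusted p = 1.03e-05). These had adjusted p = 0.927 and 0.620 with an estimated correlation.

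Xist, the RNA of the inactive X chromosome, had 24.0 and 22.2 CPM (on plain totals) in the K36M Repsox libraries and at most 4.58 in the other 6. Reads of Y-linked genes were present in all 8 libraries and were also highest in the K36M Repsox libraries, at 267 and 287 CPM, against 171 to 205 CPM in the other 6. Whether the libraries pool embryos of both sexes was not stated.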
